A study of Mus musculus with 6 samples.

How the data were processed

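RNA was measured on 6 Illumina Mouse WG-6 v2.0 expression arrays, each hybridised with biotin-labelled material made from total RNA. Per the labels, 3 arrays carried spermatogonial stem cells (SSC) isolated from testes of CD1 mice aged 6 days, and 3 carried female germline stem cells (FGSC) isolated from ovaries of CD1 mice aged 3 days. Groups and replicate numbers were taken from the sample titles. The labels do not state whether the replicates of a group came from separate animals, isolations or cultures, so the p-values measure only the spread between these samples, which may be technical. How the cells were enriched or cultured is not given in the sources used here. Organ, sex and age differ together between the groups, so their effects cannot be told apart in any comparison below.

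The authors deposited a table with the mean signal intensity and a detection p-value for each of 45281 probes on each array. Per the file headers the signal is not normalized between arrays, and the values were read as not background-subtracted, since none was negative. The authors also deposited a table of processed intensity values for the same probes. Its scale and centring were not stated. Set against the signals of the same array, its values had a rank correlation of 1.00 on each of the 6 arrays, lay on a linear scale, and followed the same distribution in all columns, with a median of 19.9 and a lowest value of 1.01, so they were read as background-adjusted and quantile-normalized intensity. These processed values were used as an alternative only. The submitters' processing notes name lumi, without a version or a role. No column of other samples was used.

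The non-normalized signals were background-corrected by the normal-exponential model with the background estimated from the detection p-values, an offset of 16 was added, and the arrays were quantile-normalized and put on the log2 scale (neqc in limma 3.58.1, R 4.3.3). Probes with a detection p-value under 0.05 on at least 3 of the 6 arrays were kept, which left 18860 probes. Gene names came from the platform annotation. Of all probes 34885 had 1 gene symbol, 18 had several and 10378 were unnamed here. Symbols were updated through a RefSeq gene table of the GRCm38 mouse assembly, with 34807 probes matched by gene ID, 11 by transcript and 67 keeping the older name. That table was used for names and chromosomes only, since the sources used here name no genome build. Probes with several genes or none were left out. Of the kept probes of a gene, the probe with the highest mean over all 6 arrays stood for the gene, which gave 10628 genes. Different probes of a gene were called in opposite directions in 232 of 3850 genes with at least 2 kept probes.

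FGSC were compared with SSC by a linear model per gene with empirical Bayes moderation (lmFit and eBayes in limma), with no covariate. Differences are FGSC minus SSC on the log2 scale, with the standard error (SE) of the fit. The p-values were adjusted by the Benjamini-Hochberg method over all genes tested, and genes with an adjusted p under 0.05 were called. A probe not detected at 0.05 on every array of a group had only a bound in that group. Its fold is given as at least the ratio of the bright group's mean to the dim group's mean, with each dim array set to the higher of the lowest detected signal on that array and the probe's own. An exact permutation test of 3 arrays against 3 has 10 splits and cannot give a p below 0.1, so none was run for single genes. The number of arrays limits the precision. Data were simulated from these arrays for the comparison of FGSC with SSC over 10628 genes. Log2 differences of 0.5, 1 and 2 were planted in 67, 67 and 66 genes. The test recovered 38.8%, 79.1% and 98.5% of them, with 9 false calls, and made 0 calls when nothing was planted. The Benjamini-Hochberg cutoff loosens as more genes change, and 6627 genes were called in the data. These rates therefore do not give the recovery in the real comparison.

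Before the data were examined, 46 gene lists were written, covering germ cell identity and stages, germ cell functions, chromatin and imprinting, somatic cells of testis and ovary, sex chromosomes and sex determination, signalling, the cell cycle, metabolism, stress and adhesion. The 43 lists with at least 5 genes tested were compared with all other genes by camera with a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with the correlation estimated from the data. The second form rests on 4 residual degrees of freedom. The rule for the genes named in the text was fixed at the same time. It takes the 12 called genes with the largest rise and the 12 with the largest fall whose groups did not overlap, up to 4 called and 2 uncalled genes of each list, all measured genes of the Y-linked and X inactivation lists, and a fixed set of germ cell and stem cell markers. Of that set, Gfra1, Stra8, Nanog and Sox2 had probes that were not kept, and H19 was not analysed here.

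The order of signals and detection p-values was checked on each array, because a detection p-value can only fall as the signal rises. Signals that had to be set aside to restore that order, and signals with over 7 significant digits, marked 658 irregular probes. On simulated arrays the check found 50 of 50 planted signals and 0 others. The probes were kept, and each affected gene named in the text is marked. Alternatives were no background correction, a normexp correction with an offset of 50, median scaling, cyclic loess, the authors' processed values, no detection filter, a detection p-value under 0.01 on all 6 arrays, the mean of a gene's probes, every kept probe by itself, the replicate number as a block, trended and robust moderation, array weights, other thresholds, and each array left out. A fit without the irregular probes was added after the data were seen. The slide of each array was not given in the sources used here, so no slide effect was fitted.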

Results

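Gene expression was compared between 2 kinds of germline stem cell preparations from newborn CD1 mice, female germline stem cells (FGSC) from the ovary and spermatogonial stem cells (SSC) from the testis. FGSC are ovarian cells described as mitotically active germ cells, and SSC are the cells that maintain sperm production. Each preparation was measured on 3 arrays, and the question was how far the genome-wide expression profiles of the 2 populations differ. The arrays detected 18574, 18660 and 18823 of 45281 probes in SSC replicates 1 to 3, and 17231, 17003 and 16198 probes in FGSC replicates 1 to 3. Median raw signals lay between 94.1 and 98.6, a background level, since most probes were undetected on each array. The 95th percentile of the raw signals was 403 on FGSC replicate 3, against 577 and 551 on FGSC replicates 1 and 2 and 464 to 572 on the SSC arrays. Below, a difference is FGSC minus SSC on the log2 scale with the SE of the limma fit, levels are means of normalized log2 signals with the SD over 3 arrays, and adjusted p-values come from limma with Benjamini-Hochberg adjustment.

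The 2 cell populations had clearly different profiles. Across the 10628 genes tested, the Pearson correlation between arrays averaged 0.989 within SSC (0.986 to 0.994), 0.971 within FGSC (0.956 to 0.994) and 0.804 between the groups (0.771 to 0.818). These are correlations across genes, which are not independent replicates. The first principal component held 87.5% of the variance and separated FGSC from SSC. The second held 8.40% and set FGSC replicate 3 apart, at 33.2 against -21.0 and -14.6 for FGSC replicates 1 and 2. In FGSC replicate 3, 149 genes lay at least 2 log2 units from the mean of replicates 1 and 2, and 146 of them were lower. Among genes with 2 kept probes that were detected on all arrays, 52 had a brightest probe that deviated this far in FGSC replicate 3, and the next probe of the same gene followed by a median of 0.201% of that deviation. For the 129 genes that differed this far between FGSC and SSC, the next probe followed by a median of 78.7%.

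**Figure D1:**
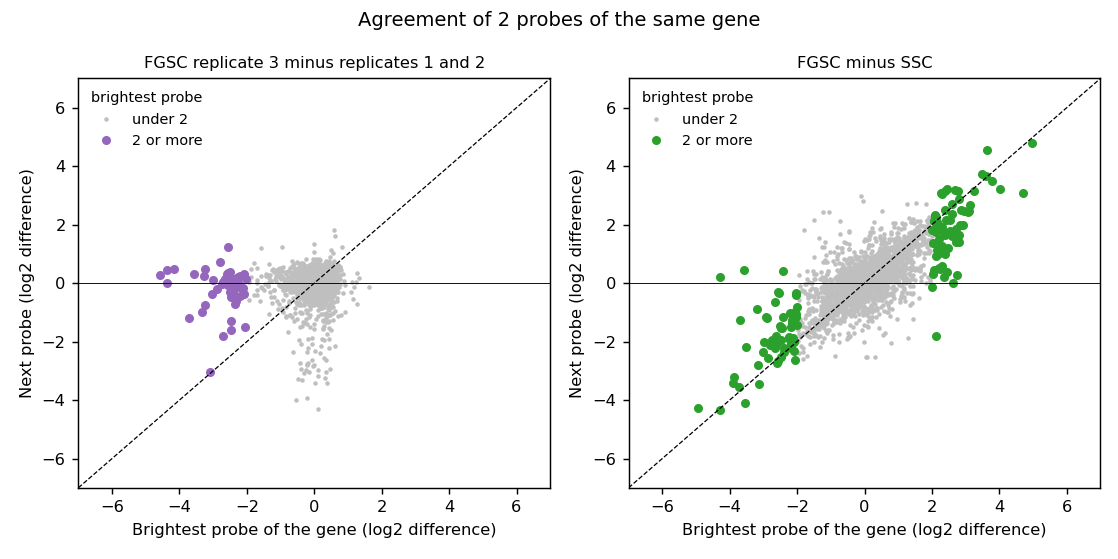
Each point is a gene with 2 probes detected on all 6 arrays, with the log2 difference of its brightest probe on the horizontal axis and that of its next brightest probe on the vertical axis, and coloured points mark genes whose brightest probe differs by 2 or more. On the left, FGSC replicate 3 is set against FGSC replicates 1 and 2 and the next probe stays near 0 for most of the 52 coloured genes, while on the right FGSC is set against SSC and most of the 129 coloured genes lie along the dashed line of equality.

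Of the 10628 genes, 6627 (62.4%) differed between FGSC and SSC, 3283 of them higher and 3344 lower in FGSC. A log2 difference of at least 1 was reached by 1338 of the higher and 1485 of the lower genes, and a difference of at least 2 by 331 and 418. All 3 values of one group lay above all 3 of the other in 70.9% of genes, where chance gives 10%. Of the 12 genes with the largest rise, 5 were on the list of oocyte genes. Nlrp5, a maternal protein of the oocyte cortex, stood at 13.58 ± 0.06 (SD, n = 3) in FGSC and 4.76 ± 0.09 in SSC, where it was detected on 1 of the arrays. Padi6, which is needed for the cytoplasmic lattices of the oocyte, was at least 326-fold higher in FGSC (adjusted p = 6.44e-08). Dppa3, a maternal factor also known as Stella, differed by 8.18 ± 0.11 and Oas1d, an oligoadenylate synthetase-like gene of the oocyte, was at least 188-fold higher. Stk32a (7.01 ± 0.07), Cd164l2 (5.98 ± 0.09), Grm4 (5.59 ± 0.14), the gap junction gene Gja4 (5.53 ± 0.10), Ap3b2 (5.50 ± 0.07) and Trp63 (5.39 ± 0.07), which guards the genome of resting oocytes, followed, together with Pinlyp and Gid4 at no less than 37.7-fold and 37.5-fold. The largest fall was that of the immediate early gene Fos, with a difference of -6.22 ± 0.17, followed by Gstm1 (-5.14 ± 0.10), Nrbp2 (-5.07 ± 0.13), Dpysl4 (-5.00 ± 0.10), the myosin light chain kinase gene Mylk (-4.95 ± 0.08), Junb (-4.92 ± 0.11) and Ret (-4.86 ± 0.09). Htra3 was at least 29.0-fold lower in FGSC, and Nt5e (-4.71 ± 0.10), Igf2 (-4.66 ± 0.12), Gpc3 (-4.65 ± 0.09) and Sel1l3 (-4.64 ± 0.13) completed the list. The balance of higher and lower genes rests on the scaling, which with median scaling moved the median of all genes to -0.12 and the split to 1929 higher and 3002 lower, 39.1% higher in place of 49.5%. Several genes named here and below were near background in one group and were detected there on 1 of its 3 arrays, namely Ap3b2, Cldn6, Nlrp5 and Wnt4 in SSC and Aldh1a1, Coro1a, Grhl2, Icam1, Nt5e, Sfrp1 and Thy1 in FGSC. Others were detected there on 2 of the 3 arrays, namely Cd164l2, Cldn4 and Dppa3 in SSC and Acrbp, Bcl6b, Gpc3, Itga6, Itgb1, Itgb5, Mcam, Ret, Sel1l3, Tcf7l2 and Tet1 in FGSC. Except for Bcl6b, Itgb1 and Thy1, whose raised signals are described below, the size and rank of their differences rest on a level close to background. The same holds for some genes detected on all 3 arrays of their dim group. Among them, Stk32a, Trp63 and Grm4 stood at 4.94, 4.90 and 5.12 in SSC, and Dpysl4 at 5.10 in FGSC.

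On some probes the deposited signal did not match its own detection p-value, which bears on several germ cell markers described below. A detection p-value ranks a probe against the array's negative controls and can only fall as the signal rises, yet 330 probes broke that order on at least 1 array. The deposited signals of 20 probes carried 9 or more significant digits on at least 1 array, and all 65 such signals with a detection p-value above 0 were out of order. They lay a median of 3.53, 3.75 and 3.82 times above the signal that the detection p-value implied on SSC replicates 1 to 3, and 3.42, 2.98 and 2.36 times above it on FGSC replicates 1 to 3. Of these 20 probes, not all of which were kept, 16 (80.0%) belonged to the germ cell and stem cell lists. Of the kept and named probes outside this set 1.31% did (odds ratio 301, 2-sided Fisher's exact test p = 6.63e-27). The 20 probes stand for Bcl6b, Cdh1, Ddx4, Id4, Itgb1, Neurog3, Pou5f1, Thy1, Zfp42 and others, and the values of these genes are marked below by raised signals or by these digits. A signal with a detection p-value of 0 has no implied signal, so whether it was raised was not measured. In all, 380 of the genes tested rested on an irregular probe, and 243 of them were called. Without the irregular probes, 6483 of 10362 genes were called, 3171 higher and 3312 lower.

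**Figure D2:**
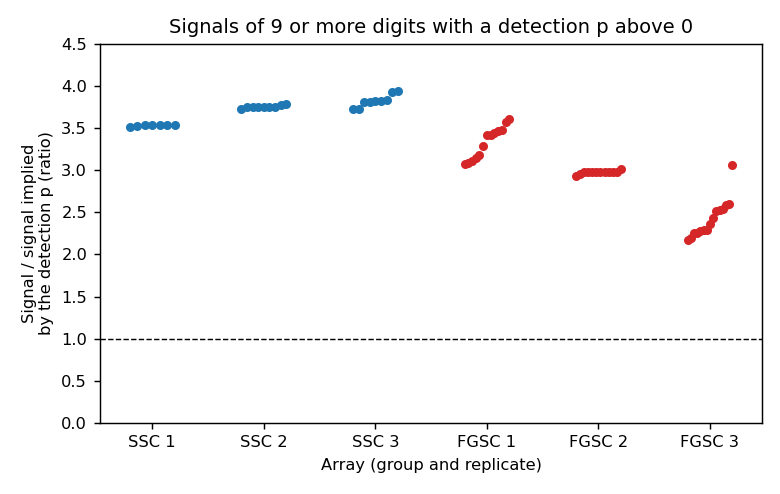
Each point is a deposited signal of 9 or more significant digits with a detection p-value above 0, plotted for its array as the ratio of the signal to the signal that other probes with that detection p-value had. The dashed line marks a ratio of 1, and all 65 points lie above 2, with medians between 2.36 on FGSC replicate 3 and 3.82 on SSC replicate 3.

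Almost all tested genes of the primordial and growing oocyte were higher in FGSC, but the detection filter favoured that direction for some of them. The list had 36 genes, and 26 were tested. Of these, 11 were detected on no SSC array, so they could pass the filter only with detection on all 3 FGSC arrays. Their direction was therefore largely set by the filter. With the stricter detection filter on every array, 10 genes of the list were left, 9 higher and 0 lower. Of 26 tested, 25 rose, 0 fell, and Nlrp14, with a difference of 0.17 ± 0.18, was not called, although its other kept probe showed 1.74 and the mean of both was a called 0.95. The median difference of the list was 3.25, also with undetected genes set to their bound, and camera placed it above all other genes (adjusted p = 5.47e-13), while the adjusted p was 0.290 with an estimated correlation. Adjusted over the list alone, 25 genes were higher as well. The transcription factor Figla, which starts zona pellucida gene expression, rose by 4.87 ± 0.11 to 10.20 ± 0.12 (SD, n = 3). The egg coat gene Zp3 rose by 3.30 ± 0.20, and Gdf9, a growth factor that oocytes secrete, by 3.22 ± 0.16. Kit, the receptor of stem cell factor on oocytes and differentiating spermatogonia, stood at 8.84 ± 0.15 in SSC and rose by 3.06 ± 0.16, and Sohlh1 rose by 2.06 ± 0.11 from an already high 11.22 ± 0.12. With all irregular probes left out, 22 of 23 oocyte genes were higher.

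**Figure D3:**
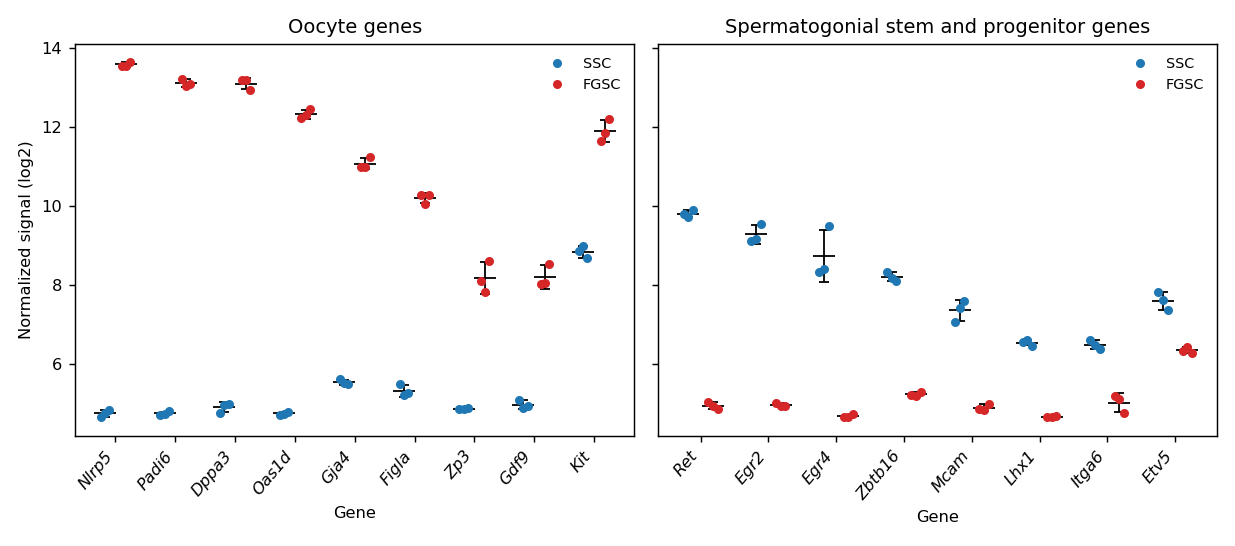
Normalized log2 signals are shown for 9 oocyte genes on the left and 8 spermatogonial genes on the right, with a point for each of 3 SSC arrays (blue) and 3 FGSC arrays (red), and black bars for the mean and SD. Nlrp5 lies near 13.58 in FGSC and 4.76 in SSC, and Ret near 4.95 in FGSC and 9.81 in SSC.

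Markers of spermatogonial stem and progenitor cells were mostly lower in FGSC. Of 23 tested, 16 fell, 3 rose and 4 were not called, and adjusted over the list alone 17 fell and 3 rose. Camera placed the list below other genes (adjusted p = 0.00240), with an adjusted p of 0.290 with an estimated correlation. Ret, the receptor tyrosine kinase for GDNF, was detected on 2 of the FGSC arrays and stood at 4.95 ± 0.08 (SD, n = 3) against 9.81 ± 0.09 in SSC. Zbtb16, a transcription factor of undifferentiated spermatogonia, differed by -2.98 ± 0.09, Mcam by -2.46 ± 0.14, Itga6 by -1.47 ± 0.14 and Etv5 by -1.24 ± 0.13. Egr2 differed by -4.31 ± 0.13, Egr4 was at least 15.2-fold lower and Lhx1 at least 3.33-fold lower in FGSC. Raised signals lie behind Bcl6b (-1.15 ± 0.13), Itgb1 (-0.84 ± 0.08), Thy1 (-0.74 ± 0.12), Id4 (-0.51 ± 0.19, not called with all arrays) and Cdh1 (-0.18 ± 0.16, not called). Thy1 was detected on 1 FGSC array by its detection p-value. Id4 was called without SSC replicate 1 (-0.72, adjusted p = 0.00453) and, closer to the threshold, in 5 other settings. With the irregular probes left out, Id4 was read from another probe and differed by 0.81, in the opposite direction, and 13 of 19 genes of the list fell while 4 rose. With the detection filter at 0.01 on all 6 arrays 11 genes of the list were left, 4 higher and 5 lower, the median was -0.18 in place of -1.15, and the list was no longer called (adjusted p = 0.916). Somatic cell markers were lower in the same comparison, with 7 of 8 genes of the Leydig and theca list, 8 of 9 of the peritubular and smooth muscle list and 11 of 16 of the endothelial list called lower. For some of these somatic genes the detection filter favoured that direction, as described below.

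Genes shared by germ cells of both sexes went both ways. Of 21 germ cell identity genes, 6 rose and 9 fell, with a median of -0.21 and a mean of 0.15, and camera did not set the list apart (adjusted p = 0.691). In this list 8 genes were read from irregular probes. Without the irregular probes 13 genes were tested, 4 higher and 5 lower, with a median of 0.003. Dnd1, an RNA-binding factor of early germ cells, differed by -2.72 ± 0.12 and Nanos3 was at least 2.84-fold lower, while the piRNA helicase gene Mov10l1 rose by 1.00 ± 0.12. Ddx4, the vasa helicase gene, gave -0.55 ± 0.09 from a probe with signals of 9 or more digits (adjusted p = 0.00211). The call was lost with median scaling (adjusted p = 0.0629). Dazl gave -0.54 ± 0.25 and was not called, except without FGSC replicate 3 (-0.79, adjusted p = 0.00887) and in a few other settings, and its other kept probe gave 1.38 in the opposite direction. Ifitm3 showed 0.00 ± 0.10. In the pluripotency list 7 of 21 genes rose and 5 fell (camera adjusted p = 0.844). Dppa5a rose by 4.97 ± 0.14, Gbx2 by 3.74 ± 0.16 and Tcl1 by 3.64 ± 0.20, while Klf4 differed by -3.27 ± 0.19 and Tet1 by -2.36 ± 0.14. Pou5f1 rose by 0.85 ± 0.19 on a probe with signals of 9 or more digits, and its regular probe showed 2.03. The list of spermatogonial differentiation held 4 higher and 10 lower genes of 16 (adjusted p = 0.155), with Upp1 at least 6.99-fold lower, Dnmt3b at -2.42 ± 0.18 and Rhox13 at -2.04 ± 0.19 against Kit, Sohlh1 and Crabp1 (1.63 ± 0.09). The filter at 0.01 on all 6 arrays left 7 genes of that list, 4 higher and 3 lower, and turned its median from -1.01 to 0.90. It left 5 higher and 5 lower germ cell identity genes, with a median of 0.03, and 6 higher and 4 lower pluripotency genes, with a median of 0.43.

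Camera set no list of meiotic and later germ cell genes apart from other genes. In meiotic prophase 8 of 20 genes rose and 8 fell (adjusted p = 0.900), with the recombination gene Mnd1 at 2.39 ± 0.11 and Mlh3 at 1.88 ± 0.14, the cohesin gene Rec8 at least 3.68-fold lower and the synaptonemal complex gene Syce3 lower as well. Spermatocyte and spermatid genes counted 2 higher and 8 lower of 13 (adjusted p = 0.479), among them Acrbp at -0.77 ± 0.11, with a median of -0.43. Of the piRNA pathway 5 of 20 rose and 8 fell (adjusted p = 0.900), with a median of -0.11 and a mean of 0.03. Irregular probes stood for 6 of these 20 genes. Without such probes 14 piRNA genes were tested, 4 higher and 5 lower, with a median of 0.01. Tdrd5 rose by 2.91 ± 0.10, and Tdrd9, read from an irregular probe, differed by -1.96 ± 0.32. Cancer-testis antigens counted 3 higher and 4 lower of 10 (adjusted p = 0.758), with Brdt at 1.51 ± 0.08. With median scaling the higher and lower genes were 4 and 7 in meiotic prophase, 0 and 8 among spermatocyte and spermatid genes, 2 and 7 in the piRNA pathway and 1 and 4 among cancer-testis antigens. With the filter at 0.01 on all 6 arrays they were 6 and 3, 0 and 2, 5 and 6, and 3 and 1 in the same order, and the median of the spermatocyte and spermatid list was 0.13. Fry found the spermatocyte and spermatid list (adjusted p = 0.0208) and the cancer-testis list (0.0133) lower on balance and the piRNA list higher (0.00512), and did not call meiotic prophase (0.670).

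Among chromatin and imprinted genes, DNA methylation and demethylation factors counted 3 higher and 8 lower of 16 (adjusted p = 0.284). Gadd45b differed by -4.12 ± 0.13, the de novo methyltransferase gene Dnmt3b by -2.42 ± 0.18 and the dioxygenase gene Tet1 by -2.36 ± 0.14, while Mbd3 rose by 1.63 ± 0.22 and the maintenance gene Dnmt1 showed -0.06 ± 0.25. Histone methylation and polycomb genes counted 8 higher and 8 lower of 24 (adjusted p = 0.797), with Cbx7 at 1.48 ± 0.12 and Mtf2 at -1.75 ± 0.15. The median of this list was 0.07 and its mean -0.02, and with median scaling the median was -0.17, with 2 genes higher and 5 lower. Paternally expressed imprinted genes counted 3 higher and 9 lower of 17, and maternally expressed ones 5 higher and 11 lower of 19 (adjusted p = 0.284 and 0.350). With median scaling the paternally expressed list held 1 higher and 8 lower genes. Gab1, at -2.99 ± 0.07, was placed on the maternally expressed list, although it has been reported as paternally expressed in the placenta, and without it that list held 5 higher and 10 lower of 18, while with it the paternally expressed list held 3 higher and 10 lower of 18. The filter at 0.01 on all 6 arrays left 2 higher and 2 lower paternally expressed genes, with a median of 0.25 in place of -0.24, and 3 higher and 4 lower maternally expressed ones, with a median of 0.08 in place of -0.29. The growth factor gene Igf2 differed by -4.66 ± 0.12, Kcnq1ot1 by -1.98 ± 0.08 and Ppp1r9a by -3.18 ± 0.11, Mest was at least 2.79-fold lower, Th was at least 9.98-fold higher, and Peg3 showed -0.07 ± 0.10.

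Markers of several somatic cell types, not all of them particular to the testis, were lower in FGSC, but the detection filter favoured that direction for some. Undetected in 1 group were 5 of 8 Leydig and theca, 1 of 9 peritubular, 6 of 16 endothelial and 8 of 18 Sertoli genes. Such genes could pass the filter only with detection on all 3 arrays of the other group. Their direction was therefore largely set by the filter. Of the Leydig and theca cell list 7 of 8 genes fell and 0 rose (camera adjusted p = 0.00240, and adjusted p = 0.290 with an estimated correlation), and of the peritubular and smooth muscle cell list 8 of 9 fell and 0 rose (0.00742, and adjusted p = 0.290 with an estimated correlation). The androgen synthesis genes Hsd17b3 and Cyp17a1 were at least 6.96-fold and 6.06-fold lower, and Mylk (-4.95 ± 0.08), Myl9 (-3.56 ± 0.11) and Smtn (-1.89 ± 0.10) fell. Acta2, at 0.08 ± 0.29, was read from an irregular probe, and its regular probe gave a called -1.46. Endothelial genes counted 1 higher and 11 lower of 16 (adjusted p = 0.0138, and adjusted p = 0.397 with an estimated correlation), with Robo4 at least 12.7-fold and Cdh5 at least 3.67-fold lower. The Sertoli cell list held 6 higher and 10 lower of 18 (adjusted p = 0.274), and with median scaling 1 higher and 12 lower (0.0305), and its hormone gene Amh was at least 12.9-fold, Fshr at least 4.37-fold and Dhh at least 3.37-fold lower. Granulosa and ovarian somatic cell genes counted 5 higher and 7 lower of 15 (adjusted p = 0.705), with Irx3 at 2.17 ± 0.07 and Wnt4 at 0.93 ± 0.16 against Inhba at -1.83 ± 0.13. Fibroblast and feeder cell genes counted 6 higher and 16 lower of 28 (adjusted p = 0.0805), with the matrix gene Sparc at -3.57 ± 0.19 and Col1a1 at -1.55 ± 0.24. This list passed without SSC replicate 1 (0.0344), without SSC replicate 3 (0.0481) and in several other settings, among them median scaling, with 3 higher and 15 lower. Macrophage and leukocyte genes counted 0 higher and 7 lower of 12 (adjusted p = 0.155), with Coro1a at -1.36 ± 0.08. Of the erythroid list 2 genes were measured, with Hba-a1 at -1.17 ± 0.11 and Slc4a1 not called. Epithelial genes ran the other way, 6 higher and 1 lower of 12 (adjusted p = 0.181), with Ovol1 at 4.04 ± 0.12, the tight junction gene Cldn4 at 3.78 ± 0.14 and Cldn6 at 1.46 ± 0.12 higher in FGSC and Grhl2 at -0.87 ± 0.08. The authors' processed values gave 5 higher and 2 lower epithelial genes. The filter at 0.01 on all 6 arrays turned the Sertoli list to 3 higher and 2 lower of 6, with a median of 0.37 in place of -0.72, and the fibroblast and feeder list to 7 higher and 4 lower of 14, with a median of 0.34 in place of -0.71 (adjusted p = 0.916 and 0.942). It left 0 called genes of 5 in the epithelial list and 1 higher and 3 lower of 5 in the granulosa list.

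**Figure D4:**
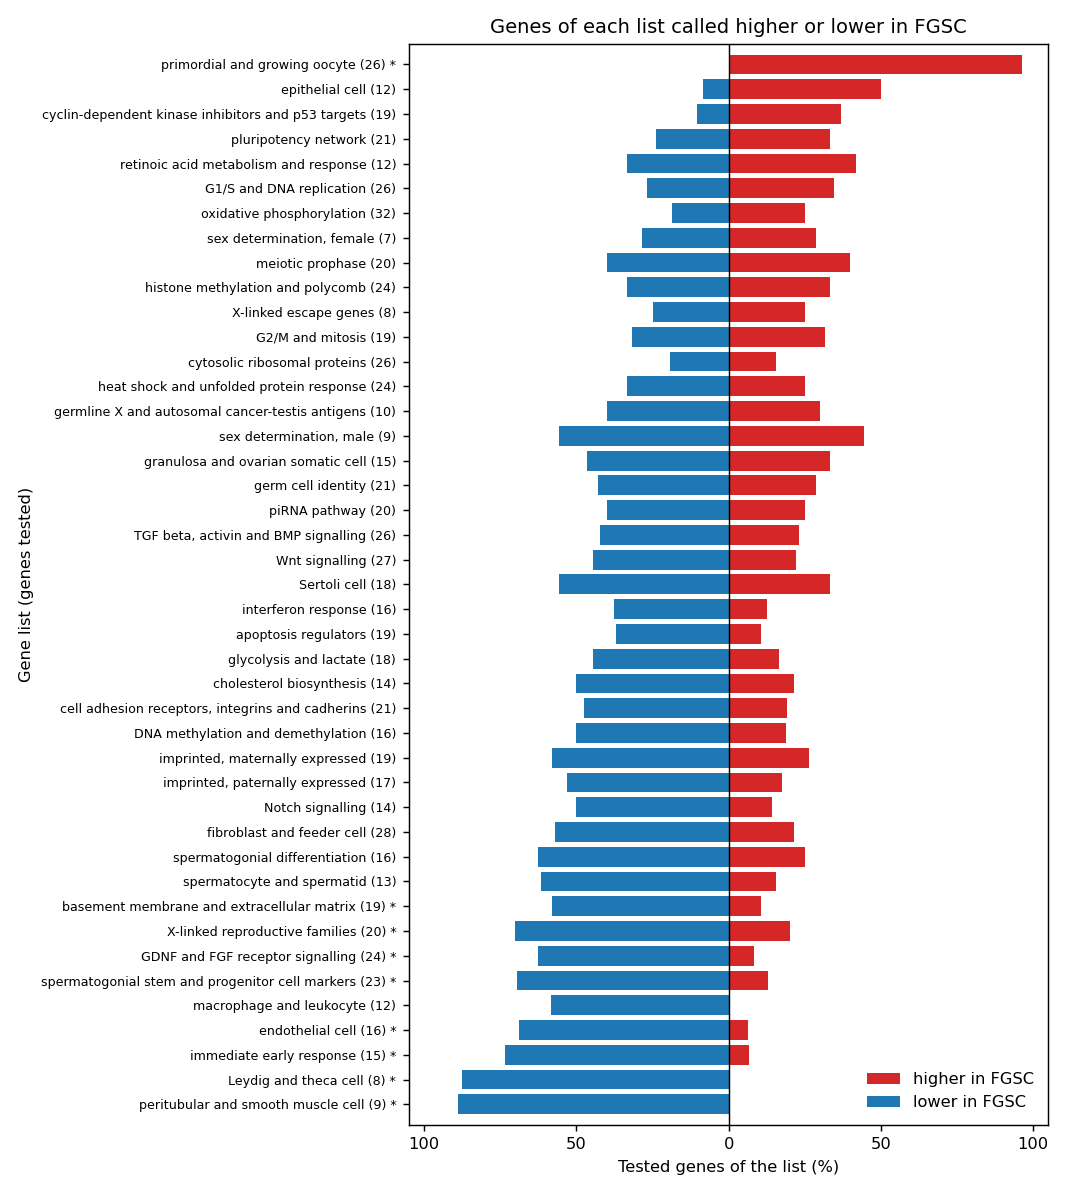
For each of 43 gene lists, bars give the percentage of its tested genes that were called higher (red, to the right) or lower (blue, to the left) in FGSC, with the number tested in parentheses and a star where camera with the preset correlation gave an adjusted p under 0.05. The oocyte list has 25 of 26 genes higher, and the peritubular and smooth muscle cell list 8 of 9 lower.

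The Y-linked transcripts that were tested were found on the arrays labelled SSC and not on those labelled FGSC, and Xist the other way round. Of 14 Y-linked genes on the list, 3 were tested, and the others had no kept probe here. The Y-linked genes Usp9y, Eif2s3y and Uty were detected on all 3 SSC arrays and on 0 of the 3 FGSC arrays. Usp9y was at least 5.81-fold and Eif2s3y at least 2.00-fold lower in FGSC (adjusted p = 1.29e-06 and 0.0108). Uty was close to background in both groups, at 4.91 ± 0.04 and 4.66 ± 0.02 (adjusted p = 0.0217), and its call was lost without SSC replicate 1 (0.0805) or 2 (0.0552) and without FGSC replicate 1 (0.0578) or 2 (0.0563), and with median scaling (0.0715). Xist, the RNA that silences an X chromosome, was not detected in SSC and was at least 1.34-fold higher in FGSC, where it stayed dim at 5.17 ± 0.18. Rlim, an X-linked activator of Xist, showed 0.02 ± 0.08. Genes on the X chromosome had a median difference of -0.14 over 375 genes, against 0.00 over 10232 autosomal genes, and the gap of -0.14 was -0.10 with undetected genes set to their bound. On X, 24.5% of genes were higher and 41.6% lower, against 31.1% and 31.1% on autosomes. Camera gave p = 0.0493, and p = 0.0379 with an estimated correlation. In the X-linked reproductive families 4 of 20 genes rose and 14 fell (adjusted p = 0.0127, and adjusted p = 0.397 with an estimated correlation), among them Magea2 at least 8.18-fold, Magea5 at least 5.58-fold and Nxf2 at least 3.74-fold lower and Mageb4 at -1.03 ± 0.09. Of the 20 genes, 6 were undetected in 1 group, so the detection filter largely set their direction. Without these families and Xist the difference of medians was -0.08, and camera with the preset correlation gave p = 0.0982. The call on all X-linked genes was lost in 11 of 20 other settings, where p with the preset correlation reached 0.0617 without SSC replicate 3 and 0.0674 without FGSC replicate 3. Genes that escape X inactivation counted 2 higher and 2 lower of 8 (adjusted p = 0.900), with a median of -0.05 and a mean of 0.11. Male sex determination genes counted 4 higher and 5 lower of 9, and female ones 2 higher and 2 lower of 7 (adjusted p = 0.450 and 0.644), with Gadd45g at -3.15 ± 0.11. With median scaling the higher and lower genes were 1 and 14 in the X-linked reproductive families, 0 and 2 among escape genes, 1 and 5 in male and 2 and 1 in female sex determination, and cyclic loess gave 3 and 6 in male sex determination. With the filter at 0.01 on all 6 arrays male sex determination genes counted 3 higher and 2 lower of 5, with a median of 0.52 in place of -0.73.

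Genes of GDNF and FGF receptor signalling and of the immediate early response were mostly lower in FGSC. Of the GDNF and FGF receptor signalling list 15 of 24 genes fell and 2 rose (camera adjusted p = 0.00240, and adjusted p = 0.397 with an estimated correlation), and adjusted over the list alone 16 fell and 3 rose. With the detection filter at 0.01 on all 6 arrays, 13 genes of this list were left, 3 higher and 7 lower, with a median of -1.21 against -1.23 for all 24, and the list was not called (adjusted p = 0.0994). Besides Fos, Ret and Egr2, the ERK phosphatase gene Dusp6 differed by -4.27 ± 0.09. Of the immediate early list 11 of 15 genes fell and 1 rose (adjusted p = 0.00184, and adjusted p = 0.397 with an estimated correlation). Junb differed by -4.92 ± 0.11, the mRNA decay factor gene Zfp36 by -4.56 ± 0.14 and Klf4 by -3.27 ± 0.19, and Atf3 was at least 6.29-fold lower. Egr1, at -1.21 ± 0.55, was not called, except without SSC replicate 1 (-1.66, adjusted p = 0.0410) and with array weights. Both lists share members. The heat shock and unfolded protein response list went both ways, with 6 higher and 8 lower of 24 (adjusted p = 0.595), from Hspb1 at -4.02 ± 0.09 to Hsph1 at 2.37 ± 0.34 and Chac1 at 1.95 ± 0.14. Wnt signalling counted 6 higher and 12 lower of 27, TGF beta, activin and BMP signalling 6 and 11 of 26, Notch signalling 2 and 7 of 14, and retinoic acid metabolism 5 and 4 of 12, with adjusted p-values of 0.440, 0.595, 0.358 and 0.900. Within them, Sfrp1 (-2.97 ± 0.10), Tcf7l2 (-2.43 ± 0.07), Tgfbr2 (-2.08 ± 0.15), Bmp4 (-1.40 ± 0.13) and the retinaldehyde dehydrogenase gene Aldh1a1 (-3.70 ± 0.34) fell, Stra6 was at least 5.50-fold lower, and the Notch ligand gene Jag2 (3.67 ± 0.20) and Id3 (1.38 ± 0.27) rose. Interferon response genes counted 2 higher and 6 lower of 16 (adjusted p = 0.358), with Ifi27 at -3.89 ± 0.09. With median scaling the higher and lower genes were 0 and 14 in GDNF and FGF receptor signalling, 3 and 10 in Wnt signalling, 2 and 4 in retinoic acid metabolism and 4 and 9 in the heat shock list. With the filter at 0.01 on all 6 arrays they were 5 and 4 in Wnt signalling, 6 and 7 in TGF beta, activin and BMP signalling, 2 and 2 in Notch signalling and 4 and 0 in retinoic acid metabolism, with medians of 0.18, 0.04, 0.01 and 0.71. The Leydig, peritubular and endothelial markers described above were lower in the same comparison.

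Camera set no list of cell cycle or energy genes apart from other genes. Genes of the G1/S phase and DNA replication counted 9 higher and 7 lower of 26, those of G2/M and mitosis 6 and 6 of 19, and cyclin-dependent kinase inhibitors and p53 targets 7 and 2 of 19, with adjusted p-values of 0.900, 0.860 and 0.644. Fry found the inhibitor and p53 list higher on balance (adjusted p = 0.00767) and the G1/S list lower (0.0404). Their medians were -0.05, 0.07 and -0.03, and those of the phase lists changed sign, to 0.02 under cyclic loess and to -0.03 under median scaling. The survivin gene Birc5 rose by 2.78 ± 0.18 and the kinase inhibitor gene Cdkn1b by 1.25 ± 0.16, Top2a differed by -2.36 ± 0.08 and Mcm4 by -1.16 ± 0.09, and Plk1 showed 0.20 ± 0.14. Oxidative phosphorylation counted 8 higher and 6 lower of 32 (adjusted p = 0.697), with Ndufa5 at 1.49 ± 0.13 and Cycs at -1.85 ± 0.09. Glycolysis counted 3 higher and 8 lower of 18 (adjusted p = 0.181), and fry found its genes lower on balance (adjusted p = 7.54e-06), with the glucose transporter gene Slc2a3 at -2.05 ± 0.10 and Aldoc at -1.98 ± 0.08. Cholesterol biosynthesis counted 3 higher and 7 lower of 14 (adjusted p = 0.358), with Srebf2 at -2.04 ± 0.10, and cytosolic ribosomal proteins 4 higher and 5 lower of 26 (adjusted p = 0.844). Apoptosis regulators counted 2 higher and 7 lower of 19 (adjusted p = 0.478), with Bik at -2.26 ± 0.11 and Bbc3, which encodes the p53 target Puma, at 2.45 ± 0.09. By fry, the cholesterol and apoptosis lists were lower on balance too (adjusted p = 0.000370 and 0.000502). Such a call was common, since fry called 33 of the 43 lists. With median scaling the higher and lower genes were 6 and 5 among kinase inhibitors and p53 targets, 0 and 8 in glycolysis and 1 and 5 among ribosomal proteins, for which cyclic loess gave 1 and 9 and the authors' processed values 3 and 6.

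Basement membrane and extracellular matrix genes counted 2 higher and 11 lower of 19 (camera adjusted p = 0.0453, and adjusted p = 0.408 with an estimated correlation), with Lama1 at -2.84 ± 0.11, Lamb2 at -2.18 ± 0.09 and Lamc1 at 0.13 ± 0.16. This call was lost without SSC replicate 2 (adjusted p = 0.0506), without FGSC replicate 1 (0.0583), with the authors' processed values (0.0582) and with the mean of a gene's probes (0.0866), with medians of -0.78, -0.61, -0.61 and -0.64 against -0.64 with all arrays. Integrins, cadherins and other adhesion receptors counted 4 higher and 10 lower of 21 (adjusted p = 0.155), with Vcam1 at least 4.39-fold lower, Icam1 at -2.32 ± 0.11 and Itgb5 at -2.03 ± 0.16. With the filter at 0.01 on all 6 arrays they counted 3 higher and 2 lower of 8, and basement membrane and matrix genes 3 higher and 8 lower of 16 (adjusted p = 0.179). The Leydig, peritubular and endothelial markers were lower in the same comparison. In all, 9 of 43 lists passed camera with the preset correlation, 1 upward and 8 downward. With the detection filter at 0.01 on all 6 arrays, which left 6896 genes, 2 lists passed, the oocyte list (adjusted p = 0.000551) and the immediate early list (0.0268), and the Leydig and endothelial lists had too few genes left to be tested. With an estimated correlation 0 passed after adjustment and 5 had an unadjusted p under 0.05, while fry, which tests whether the genes of a list move one way on balance and compares them with no other genes, called 33. Adjusted over the list alone, the counts of 31 of the 46 lists were unchanged, and no list changed by more than 3 genes.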

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

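The fit without the irregular probes was chosen after the data were seen; the other alternatives were fixed before the data were examined. For named genes, 4470 comparisons with an alternative kept their side of the threshold, with the same direction where both fits gave a call. Another 107 gained a call, 50 lost it, and 9 turned with a call in either fit. For lists these numbers were 786, 9, 18 and 0. Where neither fit gave a call, the direction was not compared, so changes of sign there are not counted as turned. Calls between FGSC and SSC ranged from 5777 without SSC replicate 2 to 7000 without FGSC replicate 3, against 6627 with all arrays and 8026 with array weights, which gave FGSC replicate 3 the low weight of 0.198, and of the 6627 at least 5725 were called in the same direction with any single array left out, 6462 without background correction, 6538 with normexp, 6318 with cyclic loess, 6471 with the authors' processed values and 4726 with median scaling, which called 1929 genes higher and 3002 lower. With a detection p-value under 0.01 on all 6 arrays, 6896 genes were tested, 4391 called, 1931 of them lower, and 2 lists passed. This filter sets a lower p-value and asks for every array together, so it removes dim genes as well as genes undetected in a group, and 0 Y-linked genes were lower because none was detected on an FGSC array. The cause of the lost list calls was not tested. Every kept probe tested by itself gave 11131 calls (5554 higher, 5577 lower), from 18860 probes in place of 10628 genes. A log2 difference of at least 1 left 2823 genes (1338 and 1485), and treat against that difference 1565 (721 and 844), as stricter demands. Camera with an estimated correlation called 0 lists.

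The difference between X-linked and autosomal medians (-0.14, camera p = 0.0493 with the preset correlation) was not called in 11 of 20 settings. It was -0.080 without background correction, -0.11 with normexp, -0.13 with cyclic loess, -0.011 with no detection filter, 0.011 with the strict one, -0.12 with the mean of a gene's probes, -0.14 with the replicate block, -0.14 with array weights and -0.081 without reproductive families and Xist, and the range with single arrays left out was -0.16 to -0.13. Over all settings the p with the preset or estimated correlation lay between 0.0228 and 0.507. The mean correlation between groups was 0.786 for the authors' values, 0.872 with no detection filter and 0.782 with the strict one. With single arrays left out it lay between 0.986 and 0.994 within SSC, and between 0.956 and 0.994 within FGSC, the latter without FGSC replicate 3. Genes that turned, with Acta2, Cenpa, Dcn and Id4 otherwise read from irregular probes, were Acta2 (-1.46), Cenpa (-0.20) and Id4 (0.81) without irregular probes, Dag1 (1.30, from an irregular probe), Dcn (0.78, also irregular) and Id4 (0.81) with the strict filter, Dcn (0.77) with the authors' values, and Fbln1 (0.32) and Hes6 (0.53) with the mean of a gene's probes. Another probe was read in the first 2 settings. For the other changes in this paragraph the cause was not tested.

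The replicate numbers did not pair the arrays: deviations of same-numbered arrays correlated at -0.20, -0.05 and -0.22 across genes, and 0 arrays correlated best with their own number. With the replicate block 5926 genes were called, 2945 higher and 2981 lower, and Uty was not called (limma adjusted p = 0.0786, between 0.000402 and 0.0805 over the alternatives). The slide as a block was not run, since the slide is not given in the sources used here. Signal over background limits dim genes: genes undetected in a group have only a bound, and setting them to it moved the median of a list by at most 0.13.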

Other observations

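All tests in this part were chosen after the result was seen, except camera on the lists and the test of somatic cell lists in FGSC replicate 3. The other scalings were planned, but setting them against the oocyte list was not. Of the 10 splits of the 6 arrays into 3 and 3, 1, the real one, called 6627 genes and the highest of the others called 0. With 10 splits the share cannot fall under 0.05. Each of the other splits put arrays of both populations on either side. The difference between the populations then counted as spread within a side, so the 0 calls there say nothing about chance.

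By chromosome, the autosomes differed little in their balance of genes higher and lower in FGSC. Autosomal medians lay between -0.07 on chromosome 3, where 27.6% of 474 genes were higher and 34.8% lower, and 0.07 on chromosome 6, where 32.5% of 532 genes were higher and 29.1% lower. Chromosome 8 had the highest share of higher genes (35.5% of 591). The X chromosome lay outside that range at -0.14. These values were read after the fact and no autosome was tested against the others.

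The oocyte list was the only one of 43 that camera with the preset correlation placed higher in FGSC, while its adjusted p was 0.290 with an estimated correlation. Irregular probes do not account for it, since only 3 of the 26 tested genes were read from them, too few to move the median far. The list's median was 3.29 without them (lower quartile 2.08). Neither does the scaling account for the rise, since the lowest median over 5 other scalings was 1.86, without background correction. Whether the FGSC preparations held oocytes, or the stem cells themselves held these transcripts, cannot be told apart, since 25 of 26 genes would be higher either way and no list separates the 2 sources. Nlrp5, Padi6 and Dppa3 stood at 13.58, 13.11 and 13.10 in FGSC and Sohlh1 at 13.28, each on its own probe, 12 of the 26 genes were detected on all SSC arrays and 4 are also on another list. Organ, sex and age stay open as untested, as does any sorting step that would have removed oocytes, which is not given in the sources used here.

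FGSC replicate 3 lay at least 2 log2 units from replicates 1 and 2 in 149 genes, 146 of them lower, and 17 of the 149 were called between FGSC and SSC. A change in the amount of whole transcripts is argued against, since the next probe of the same gene followed by a median of 0.201% over 52 genes, against 78.7% over the 129 genes that differed as far between the groups. The somatic list with the largest median deviation, that of granulosa cells, lay at 0.074 log2 units. This cannot exclude another share of somatic cells. Many genes of these lists were undetected in a group, 5 of 8 in the Leydig and theca list and 8 of 18 in the Sertoli list. Those at background in FGSC had no room to fall. A fault of single probes on that array may lie behind the pattern, while a change confined to some isoforms stays open, and neither was tested. No biological explanation is given by the design, which puts the 3 arrays in 1 group.

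The 20 probes with signals of 9 or more digits were mostly for germ cell and stem cell markers. Of their 110 signals of this kind, 65 had a detection p-value above 0, and these 65 lay above the signal that it implied. For the other signals no implied signal exists. Random error of single signals is argued against, since the lowest of the 65 ratios was 2.17. Within an array the highest ratio exceeded the lowest by 1.01 to 1.17 times on 5 arrays and by 1.41 times on FGSC replicate 3. A candidate explanation is that these signals were multiplied by about 1 factor per array after the detection p-values were computed, in a step that the sources used here do not describe. The median ratio was 3.53 or more on the SSC arrays and 3.42 or less on the FGSC arrays. Factors of these sizes would shift the differences of these genes toward lower in FGSC, by an amount that was not estimated. No biological explanation was tested.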
